A study of Homo sapiens with 12 samples.

How the data were processed

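RNA of 12 samples of Ls174T derivatives was hybridised to Affymetrix U133 Plus 2.0 arrays, 1 array per sample. Per the labels, cells grew in RPMI medium with fetal calf serum, and RNA was extracted with Trizol and cleaned on RNeasy columns. The 4 groups, with 3 arrays each, were the β-catenin shRNA line uninduced and after 72 h of induction, and the dominant-negative Tcf4 line uninduced and after 24 h of induction. The labels number the arrays of each group but do not say whether the numbers pair samples or whether arrays came from separate cultures.

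The deposited table gives 1 value per probe set and array, an intensity (signal) on a linear scale in arbitrary units. Per the labels, MAS5 and GCOS were used, and their versions are not given in the sources used here. On every array the mean over the middle 96% of probe sets was 100.0, as left by the authors' scaling. The values carry no detection calls, and between 6.58% and 9.25% of values per array lay under 1. The table holds 54675 probe sets, 62 of them Affymetrix controls, and no column was left unused. No genome build is given in the sources used here, so no coordinates are reported.

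Probe sets were paired with genes through an annotation of the array. Of all probe sets 41097 had exactly 1 gene symbol, 1801 had several and 11777 were unnamed here. The Entrez numbers of 54 probe sets were not found in the gene table used to update symbols. Values under 1 were set to 1 and log2 was taken. For each of 19775 genes the probe set with the highest mean log2 signal over the 12 arrays was kept, among those with 1 symbol. Genes were tested if that mean was at or above the median over all probe sets, 3.35, which is a signal of 10.2. This kept 12386 genes and left out 7389.

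A linear model with 4 group means was fitted with limma 3.58.1 in R 4.3.3 (8 residual degrees of freedom), with empirical Bayes moderation and a variance trend (prior degrees of freedom 8.05). There were 4 contrasts: induced minus uninduced in each line, the difference of these changes (shRNA minus dominant-negative Tcf4), and the uninduced dominant-negative Tcf4 line minus the uninduced shRNA line. P-values are two-sided and adjusted by Benjamini and Hochberg over the genes tested in each contrast, and a gene was called at an adjusted p under 0.05. The probe sets of CTNNB1 and TCF7L2 were read from a second fit of the same model over all probe sets except the controls. Overlaps of called genes were compared with the product of the shares and with Fisher's exact test.

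A total of 23 gene lists, written from general knowledge before the data were examined, were tested with limma's camera at its preset correlation of 0.01 between genes, adjusted over 46 tests (each list in each induction). The same was done for the difference of the changes. Of the 569 entries 524 paired with a probe set of 1 symbol, and 45 did not and were not analysed here. Counts of members are given over all genes tested and adjusted over the list alone. In 24 of the 46 tests a list was called, and 18 of these were also called with an estimated correlation. The calls that were lost are named beside their lists.

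Genes were named by a rule. It took all probe sets of CTNNB1 and TCF7L2, and in each induction the 12 largest decreases and 10 largest increases among called genes without overlap of induced and uninduced values. It also took up to 4 called members per list and induction, and all called Wnt/TCF targets. Finally it took the 12 largest shared decreases, the 12 largest shared increases, the 6 largest opposite changes, the 10 largest differences of change, and 6 genes per direction between the uninduced lines. Some members of the lists, such as those moving against their list or those missing the test, were named in addition after their values were seen. In the list of 6 opposite changes genes are ranked by the smaller of both changes.

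The lists, the rule, the tests of genes and lists and the alternatives were fixed before the data were examined. Tests of explanations and of gene families chosen or altered later are named where they are given. Alternatives were quantile normalization, centring each array on its median, an offset of 3.5 (the median over arrays of the 25th percentile of signal) before log2, no filter, and a stricter filter at the 75th percentile (6.29, a signal of 78.2). Others were every probe set by itself, no probe sets ending in _x_at or _s_at, no variance trend, array quality weights, only the arrays compared, the replicate number as a block, and a minimum change of 2-fold. Lists were also tested with an estimated correlation and with fry, and each of the 12 arrays was left out in turn.

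The steps were tested on simulated data with 200 altered genes per line. Of 100 genes altered 2-fold, 73% were recovered in the shRNA arm and 70% in the dominant-negative Tcf4 arm, and of 100 altered 4-fold, 93% and 88%. There were 9 false calls among 175 and 6 among 164, and the 1 altered list was called in each arm with no other. The simulated noise had no correlation between genes and no floor, and far fewer genes were altered than were called in the data. False list calls that arise from correlated genes are therefore not measured by it. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9. Arrays carry no read depth, so the number of arrays and the distance of a signal from background set the precision.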

Results

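RNA was measured on 12 Affymetrix U133 Plus 2.0 arrays from derivatives of Ls174T, a human colorectal carcinoma line in which the Wnt pathway is constitutively active. In 1 derivative doxycycline switches on a short hairpin RNA (shRNA) against β-catenin, the protein that Wnt signalling stabilises. In the other it switches on a dominant-negative Tcf4, a form of the DNA-binding partner of β-catenin that blocks transcription through it. Each line gave 3 uninduced and 3 induced arrays, taken 72 h after induction of the shRNA and 24 h after induction of dominant-negative Tcf4. The question behind the design is which genes of these cells depend on Wnt signalling. The labels do not say whether arrays of a group came from separate cultures, so the p-values of single genes measure the spread between arrays only. Those of lists compare the members with other genes, and those of overlaps count genes. The 3 arrays per group limit the precision.

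Each array held a signal for 54675 probe sets. Median signals per array lay between 12.1 and 15.3, and the highest signals between 10479.0 and 16510.8. Pearson correlations between arrays of the same group, across probe sets with a mean log2 signal at or above the median, ranged from 0.958 to 0.969. After reduction to 1 probe set per gene and a filter on dim genes, 12386 genes were tested. Principal components were taken over the probe sets used for the correlations. The first, with 39.96% of the variance, separated the lines, and the second, with 19.62%, separated induced from uninduced arrays in both. Signals are given as geometric means of 3 arrays, and log2 changes as induced minus uninduced ± standard error.

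Probe sets of CTNNB1 and TCF7L2 were read first, as a measure of the constructs. The brightest of 3 probe sets for CTNNB1, the gene of β-catenin, fell from a signal of 3784 ± 195 to 156 ± 21.4 (arithmetic mean ± SD, n = 3) when the shRNA was induced, a 24.4-fold decrease with a log2 change of -4.61 ± 0.11 and an adjusted p of 5.15e-14. The next brightest fell by 3.92, from 342 to 22.8, and the dimmest, at 61 before induction, had a change of -0.54 that did not pass (adjusted p = 0.21). With dominant-negative Tcf4 the brightest CTNNB1 probe set had a change of 0.17 ± 0.11 that did not pass (adjusted p = 0.42). TCF7L2, the gene for Tcf4, is covered by 7 probe sets. On induction of dominant-negative Tcf4 1 of them rose 11.6-fold, from 108 ± 29.5 to 1286 ± 499, and another 7.55-fold, from 407.9 ± 21.3 to 3128 ± 709. Smaller increases of 0.72, 0.67 and 0.48 were seen with 3 other probe sets, which rose by 0.74, 0.64 and 0.54 with the β-catenin shRNA as well. The probe set with the 7.55-fold rise also rose with the shRNA, by 0.63 (adjusted p = 0.0064), whereas that with the 11.6-fold rise did not pass there (0.49, adjusted p = 0.23). For the remaining TCF7L2 probe sets, 1 did not pass in either line (0.48 with the shRNA and 0.41 with dominant-negative Tcf4) and 1 lay below the filter.

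**Figure D1:**
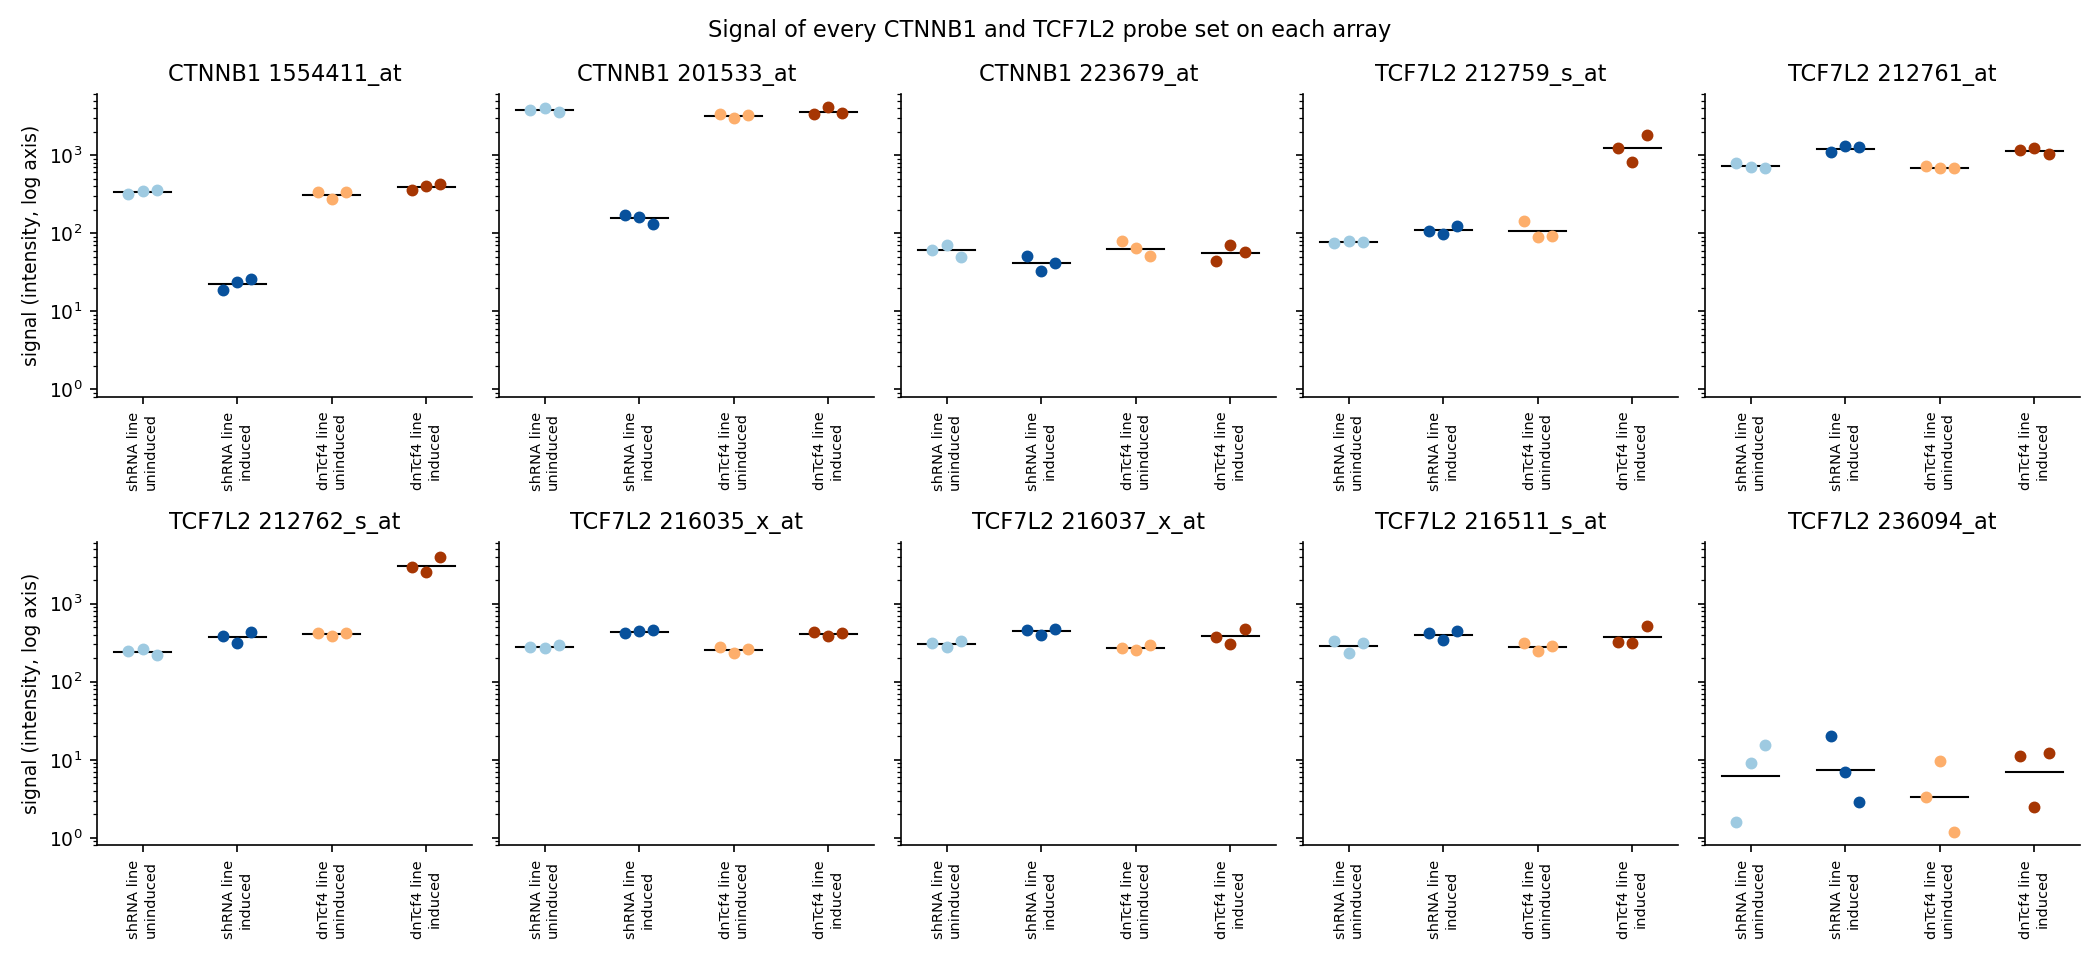
Signal of each array (points, log10 axis, arbitrary intensity units; lines are geometric means) for the probe sets of CTNNB1 and TCF7L2 in the 4 groups of 3 arrays. The brightest CTNNB1 probe set fell 24.4-fold with the shRNA, and TCF7L2 probe sets rose up to 11.6-fold with dominant-negative Tcf4.

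Induction of the β-catenin shRNA for 72 h lowered established Wnt targets, crypt stem cell genes and most listed genes of DNA replication and mitosis. Among the genes that rose most in this line were genes of differentiated intestinal epithelium. FABP1, the fatty acid binding protein of absorptive enterocytes, rose 151-fold from a signal of 16.7 to 2510, and KRT20, a keratin of mature surface epithelium, rose 101-fold from 24.5 to 2480. CEMIP, a hyaluronan-binding protein, fell 11.5-fold, and ASCL2, the transcription factor that maintains intestinal stem cell identity, fell 8.42-fold. Of the genes tested, 4217 (34.05%) changed, 2059 upward and 2158 downward, among them 533 and 535 with at least a 2-fold change. With each array centred on its median the split was 1481 upward and 2066 downward of 3547.

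The 12 largest decreases without overlap between the 3 induced and 3 uninduced values began with CTNNB1 itself and CEMIP (log2 change -3.52 ± 0.17). RETNLB, a resistin-like protein secreted by goblet cells, fell by 3.49 ± 0.63, and DEFA6, a defensin of Paneth cells, fell by 3.36 ± 0.48, both to signals under the filter (8.35 and 2.91). ASCL2 fell by 3.07 ± 0.17, and ACSL5, an acyl-CoA synthetase of the gut, by 3.06 ± 0.13. LRP4, a receptor that binds modulators of Wnt signalling, fell by 2.89, PNMA3, of the paraneoplastic antigen family, fell by 2.88, TMEM80 fell by 2.78, and GPR3, a constitutively active G protein-coupled receptor, fell by 2.75. The antisense transcript DEPDC1-AS1 fell by 2.73 ± 0.70 to a signal of 2.8. B3GAT1, the enzyme that builds the HNK-1 carbohydrate, fell by 2.64 ± 0.81 and had the largest adjusted p of the 12 (0.019). Its call was lost without shRNA induced replicate 1 (-1.85) or 3 (-2.42), or uninduced replicate 1 (-2.66) or 2 (-2.58). Changes that end near the floor are less exact: with an offset of 3.5 added to every signal they were -2.33 for DEFA6, -2.08 for GPR3 and -1.73 for DEPDC1-AS1.

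The 10 largest increases started from low signals. After FABP1 (7.23 ± 0.23) and KRT20 (6.66 ± 0.26) came IL1R2, a decoy receptor for interleukin 1, which rose 88.2-fold to 1810, and ISX, an intestinal homeobox factor, which rose 66.9-fold from 9.12 to 610. TNNC1, a troponin of muscle, rose from 5.15 to 214, and IL33, an epithelial alarm cytokine, from 5.8 to 235. TM4SF4, a membrane protein with 4 transmembrane segments, rose from 2.45 to 98.9, and AKR1B10, an aldo-keto reductase, rose 32-fold to 976. TFF2, a trefoil peptide, rose from 4.89 to 154, and ARL14, a small GTPase, from 8.97 to 279. The largest adjusted p among these 10 was 3.40e-08. With the same offset the folds of the dimmest genes shrank, from 41.5 to 24.2 for TNNC1, from 40.5 to 24.3 for IL33, from 40.3 to 16.9 for TM4SF4, and from 31.5 to 18.7 for TFF2.

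Of 24 tested Wnt/TCF target genes, 19 fell and none rose with the β-catenin shRNA, 19 also when adjusted over the list alone, with a median log2 change of -1.03 (adjusted p = 4.68e-13). EPHB3, an ephrin receptor of crypt cells, fell by 2.55 ± 0.11, AXIN2, the negative feedback scaffold of the pathway, by 1.60 ± 0.15, and LGR5, the R-spondin receptor of crypt base stem cells, fell by 1.55 ± 0.12. ETS2, a transcription factor, fell by 1.55, and the pathway inhibitor APCDD1 fell by 1.87. ZNRF3 and RNF43, ligases that remove Wnt receptors from the membrane, fell by 1.20 and by 1.07. PHLDA1 and SLC12A2 each fell by 1.17. The oncogene MYC fell by 0.99 ± 0.09, MYB fell by 0.95, and CCND1, encoding cyclin D1, fell by 0.88. BMP4 fell by 0.75, SOX4 fell by 0.73, SOX9 fell by 0.63, and the adhesion receptor CD44 fell by 0.37. NKD1, an inhibitor acting on Dishevelled, fell by 1.73 ± 0.59, and its call was lost without shRNA induced replicate 1 (-0.97), uninduced replicate 1 (-1.46) or uninduced replicate 3 (-1.73), and with no filter on dim genes (-1.73). LEF1 (-0.74, adjusted p = 0.25), DKK1 (0.66, adjusted p = 0.13) and BAMBI (-0.04, adjusted p = 0.87) did not pass.

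**Figure D2:**
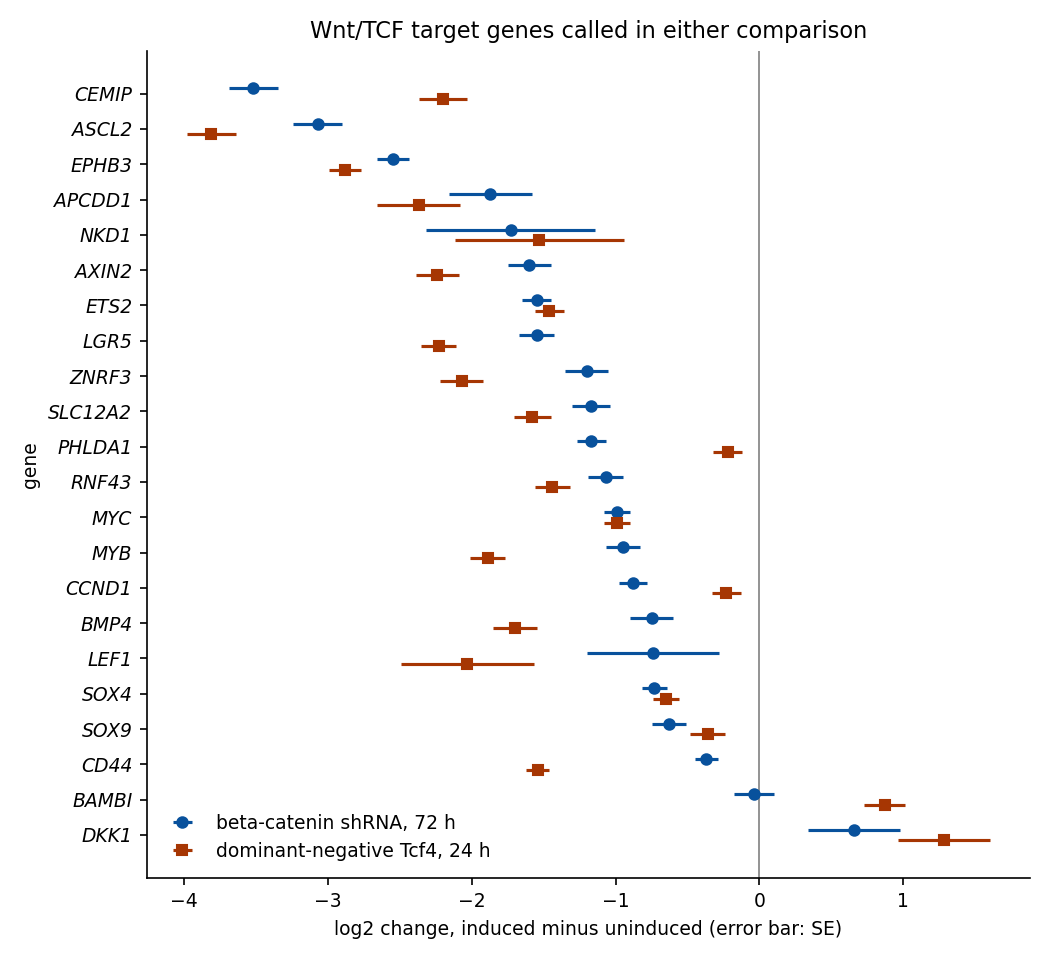
Log2 change (x axis, induced minus uninduced; bars are standard errors, 3 arrays per group) of the Wnt/TCF target genes called in either comparison (y axis) with the β-catenin shRNA at 72 h and dominant-negative Tcf4 at 24 h. ASCL2 fell most with dominant-negative Tcf4 (-3.81) and CEMIP with the shRNA (-3.52), while DKK1 and BAMBI lay above 0 with dominant-negative Tcf4 (1.28 and 0.87).

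Intestinal stem cell markers fell as a list, 10 of 14 tested members lower and 2 higher (12 lower and 2 higher when adjusted over the list alone; median -1.31, adjusted p = 5.94e-07). The entries ASCL2, LGR5, AXIN2, RNF43, SOX9, CD44, EPHB2 and TNFRSF19 are also on the Wnt/TCF target list, so these lists are not separate evidence. LRIG1, a feedback inhibitor of growth factor receptors, fell by 2.54, and RGMB, a BMP co-receptor, and SMOC2, a matricellular protein of the crypt base, each fell by 2.42. ALCAM and CD24 rose, by 0.87 and 0.94. Markers of differentiated cells moved the other way. Among 19 absorptive enterocyte markers 10 rose and 2 fell (10 and 3 when adjusted over the list alone; median 1.08, adjusted p = 8.03e-04). CA1, a cytosolic carbonic anhydrase of colonocytes, rose by 4.76, MALL, of the raft-associated MAL family, rose by 3.13, and SLC5A1 and HSD11B2 fell by 1.31 and by 1.66. Of 21 goblet cell markers, 15 rose and 1, RETNLB, fell (16 and 1 when adjusted over the list alone; median 1.23, adjusted p = 6.54e-08). TFF1 rose by 4.02, ZG16, a lectin of mucus granules, by 3.62 ± 0.78, and MUC2, the main secreted mucin of the colon, by 3.35. Paneth cell markers went both ways: PRSS2, a trypsinogen, rose by 2.59, while DEFA6 fell by 3.36, the lectin REG1A by 1.75, REG3A by 1.56 and PLA2G2A, a secreted phospholipase, fell by 0.55. That made 1 of 5 higher and 4 lower, also when adjusted over the list alone (median -1.56, adjusted p = 0.14), and the list passed without _x_at and _s_at probe sets (-1.75). None of 3 enteroendocrine markers passed, nor when adjusted over the list alone, and their median (0.11) differed in sign from their mean (-0.04) and from the direction of the test, down (adjusted p = 0.87).

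Of 40 genes of DNA replication and the G1/S transition 39 fell and none rose, 39 also when adjusted over the list alone (median -1.52, adjusted p = 8.35e-33). GINS4 and GINS2, of the replicative helicase complex, fell by 2.19 ± 0.40 and by 2.04 ± 0.10, the initiation factor MCM10 by 2.02 and ORC1, of the origin recognition complex, by 2.01. The decrease of GINS4 was -1.44 without shRNA induced replicate 2, and that of GINS2 was -1.11 and did not pass without _x_at and _s_at probe sets. Of 29 mitosis genes 27 fell and none rose, 28 lower when adjusted over the list alone (median -1.34, adjusted p = 2.10e-23). BIRC5, the survivin subunit of the chromosomal passenger complex, fell by 1.82, CENPF, a kinetochore protein, by 1.72, CCNA2, cyclin A, by 1.69, and the spindle protein ASPM by 1.58. Of 27 ribosome biogenesis genes 13 fell, also 13 when adjusted over the list alone (median -0.34, adjusted p = 4.57e-05). Among them LYAR fell by 1.37, RRP9 by 1.25, and NOLC1 fell by 0.68. Genes of nucleotide and polyamine synthesis counted 13 lower of 23, again 13 when adjusted over the list alone (median -0.37, adjusted p = 1.12e-05), a call lost at adjusted p = 0.17 with an estimated correlation. GMPS, the last enzyme of GMP synthesis, fell by 0.97, and PRPS2 and CTPS1 fell by 0.87 and by 0.79.

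Interferon response genes rose with the shRNA, 14 of 22 higher and 2 lower, the same counts when adjusted over the list alone (median 0.81, adjusted p = 2.25e-04). This call was lost with an adjusted p = 0.1 with an estimated correlation, and also under the stricter filter on dim genes (0.60). IFI27 rose by 2.11, IRF9, a subunit of the interferon-activated factor ISGF3, by 1.78, and IFIT3 and IFIT2, which bind viral RNA, by 1.66 and 1.60. Cell junction genes rose as well, 11 of 25 higher and 2 lower, also when adjusted over the list alone (median 0.18, adjusted p = 0.005). CDH17, an intestinal cadherin, rose by 2.27 and CLDN4, a barrier-forming claudin, by 1.39, whereas CLDN2, a pore-forming claudin of crypt cells, fell by 2.04 and NECTIN1 by 1.32.

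The remaining lists did not pass with the β-catenin shRNA. Wnt pathway components had 3 of 31 higher and 7 lower, also when adjusted over the list alone (median -0.07, adjusted p = 0.6), with DVL2, a Dishevelled, at -0.83 and FZD3, a Wnt receptor, at -0.75. Among 22 p53 target and CDK inhibitor genes 7 rose and 5 fell (9 and 5 when adjusted over the list alone; median 0.11, adjusted p = 0.41). CDKN2B, which inhibits CDK4 and CDK6, rose by 3.94 ± 0.32 from 10.1 to 155, and CDKN1C fell by 2.00. ATF4 and ER stress genes had 5 of 22 higher and 8 lower (5 and 10 when adjusted over the list alone; median -0.26, adjusted p = 0.25), with the chaperone DNAJB9 at 1.27 and the amino acid synthesis enzymes ASNS and PHGDH at -1.08 and -0.98. Cholesterol synthesis genes had 2 of 16 higher and 1 lower, also when adjusted over the list alone (median 0.05, adjusted p = 0.6). SREBF2, a regulator of that pathway, fell by 0.70, and STARD4, a sterol carrier, rose by 0.69. Hypoxia and glycolysis genes had 1 of 21 higher and 4 lower (0 and 3 when adjusted over the list alone; median -0.07, adjusted p = 0.47), with the angiogenic factor VEGFA at -1.02. MAPK output and immediate early genes had 8 of 22 higher and 5 lower, also when adjusted over the list alone (median 0.25, adjusted p = 0.38). The ERK phosphatase DUSP5 rose by 2.73 and the feedback inhibitors SPRED1 and SPRY2 by 1.42 and 1.32, and the list passed without _x_at and _s_at probe sets (0.71). Notch pathway genes had 4 of 17 higher and 6 lower, also when adjusted over the list alone (median -0.18, adjusted p = 0.3). NRARP, a Notch feedback inhibitor, fell by 1.34, DLL1 by 1.15 and NOTCH1 by 1.12, JAG1 rose by 0.92, and the list passed without _x_at and _s_at probe sets (-0.59). BMP and TGF-beta response genes split evenly, 4 of 18 higher and 4 lower, also when adjusted over the list alone (median -0.06, adjusted p = 0.53). ID3 and ID1, inhibitors of differentiation induced by BMP, fell by 2.63 and by 2.37, and SMAD9 fell by 2.11.

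Markers of other cell types and reference genes were measured beside these. With the shRNA 2 of 7 fibroblast markers rose, also when adjusted over the list alone (median 0.17, adjusted p = 0.41): ACTA2, smooth muscle actin, rose by 0.92, and LUM, lumican, rose by 1.94 from 4.52 to 17.3, a call lost when only the arrays compared were fitted. Of 7 leukocyte markers 1, the actin regulator CORO1A, fell (by 1.31), also when adjusted over the list alone (median -0.42, adjusted p = 0.64). Of 11 reference genes 2 rose and 2 fell, also when adjusted over the list alone (median 0.10, adjusted p = 0.6): B2M rose by 0.54 and YWHAZ by 0.42, and SDHA fell by 0.42.

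The test behind these calls was limma's moderated statistic with an adjusted p under 0.05. No array given doxycycline without a construct was used here, so the effect of the inducer is not separated from that of the shRNA.

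Dominant-negative Tcf4 for 24 h lowered Wnt targets and stem cell genes, and with them genes of ribosome biogenesis, nucleotide synthesis and DNA replication. The largest increases were those of GUCA2B and GUCA2A, which encode intestinal peptides. GUCA2B, uroguanylin, rose 167-fold from a signal of 5.19 to 868, a fold of 88.2 with the offset of 3.5, and GUCA2A, guanylin, rose 60.8-fold from 21.8 to 1330. ASCL2 fell 14-fold from 1250 to 89. In this line 4455 genes (35.97%) changed, 1981 upward and 2474 downward, of which 609 and 327 changed at least 2-fold.

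Among the 12 largest decreases without overlap, C2CD4A, a nuclear protein with a C2-like domain, fell by 4.06 ± 0.34, from 160 to 9.61, and ASCL2 fell by 3.81 ± 0.17. KCNT1, a sodium-activated potassium channel, fell by 3.30, OR51E1, an olfactory receptor, by 3.18 and C6orf141 fell by 3.01, all ending below a signal of 10.2, the filter on dim genes. EPHB3 fell by 2.88 ± 0.11, from 516 to 70.1. RETNLB fell by 2.63 ± 0.63, PNMA3 by 2.52, ODAM, a secreted protein of enamel-forming cells, by 2.48 and SMOC2 fell by 2.43 ± 0.23. The noncoding LINC00910 and the kinesin KIF21B fell by 2.43 ± 0.67 and by 2.42 ± 0.66 to signals of 2.39 and 2.52, with the largest adjusted p of the 12 (0.0089), and both calls were lost when only the arrays compared were fitted. With the offset the changes were -1.93 for KCNT1, -2.16 for OR51E1, -1.72 for C6orf141, -1.65 for RETNLB, -1.43 for LINC00910 and -1.42 for KIF21B.

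Among the 10 largest increases, GUCA2B had a log2 change of 7.39 ± 0.81, which was 6.20 without uninduced replicate 2, whose signal was at the floor, and GUCA2A 5.93 ± 0.70. ZBTB7C, a zinc finger repressor, rose from 4.23 to 164, and MUC17, a mucin of the enterocyte membrane, from 8.91 to 342. KRT13, a keratin of stratified epithelium, rose from 6.54 to 228 with the largest adjusted p of the 10 (3.25e-04). WFDC21P, a transcribed pseudogene, rose from 7.55 to 230, GDPD3, a lysophospholipase D, from 4.62 to 115, and AHNAK2, a large scaffold protein, from 11.5 to 286. RSAD2, the antiviral protein viperin, rose 22.8-fold from 12.6 to 289. MUC5AC, a gastric mucin, rose by 4.57 ± 0.57 from 10 to 238, but a different probe set, used when _x_at and _s_at probe sets were left out, changed by 0.33 and did not pass. With the offset the folds were 20.5 for ZBTB7C, 27.4 for MUC17, 21 for KRT13, 20.6 for WFDC21P and 12.6 for GDPD3.

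Of the 24 Wnt/TCF target genes, 17 fell and 2 rose with dominant-negative Tcf4 (21 lower and 2 higher when adjusted over the list alone; median -1.56, adjusted p = 4.57e-12). After ASCL2 and EPHB3 the largest decreases were APCDD1 (-2.37 ± 0.29), AXIN2 (-2.24 ± 0.15), LGR5 (-2.23 ± 0.12), CEMIP (-2.20 ± 0.17) and ZNRF3 (-2.07 ± 0.15). LEF1, a partner of β-catenin of the same family as Tcf4, fell by 2.03 ± 0.46, and its change was -1.27 without dominant-negative Tcf4 induced replicate 3. MYB fell by 1.89, BMP4 by 1.70, SLC12A2 by 1.58, CD44 by 1.54, ETS2 by 1.46 and RNF43 fell by 1.44. MYC fell by 0.99 ± 0.09 and SOX4 by 0.65. SOX9 fell by 0.36 ± 0.12, and its call was lost without dominant-negative Tcf4 induced replicate 1 (-0.30), induced replicate 2 (-0.25) or uninduced replicate 1 (-0.26), when only the arrays compared were fitted, and without the variance trend. The Wnt antagonist DKK1 rose by 1.28 and BAMBI, a decoy receptor for TGF-beta family ligands, by 0.87. PHLDA1 (-0.22, adjusted p = 0.11), CCND1 (-0.23, adjusted p = 0.071) and NKD1 (-1.53, adjusted p = 0.052) did not pass.

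Stem cell markers, which share entries with the Wnt/TCF targets, fell in this line too, 11 of 14 lower and 1 higher, also when adjusted over the list alone (median -1.37, adjusted p = 4.05e-07). CD24, a surface glycoprotein, was the member that rose, by 2.95. Absorptive enterocyte markers rose, 12 of 19 higher and 2 lower, also when adjusted over the list alone (median 1.16, adjusted p = 8.29e-04). FABP1 rose by 3.66, MALL by 3.39, KRT20 by 2.03 and CA2, a carbonic anhydrase, by 1.53, and SLC5A1 and HSD11B2 fell by 1.71 and by 1.58. Goblet cell markers rose, 12 of 21 higher and 2 lower (15 and 2 when adjusted over the list alone; median 1.16, adjusted p = 3.67e-07). KLF4, a factor of goblet cell maturation, rose by 2.35, MUC2 by 2.15, TFF1 by 2.07, and MUC5B by 3.04 from 1.63 to 13.4 (1.75 with the offset), and RETNLB and ST6GALNAC1 fell. Of 5 Paneth cell markers only PLA2G2A passed, and it fell by 1.92, also when adjusted over the list alone (median -0.57, adjusted p = 0.3). Of 3 enteroendocrine markers 1, the homeobox factor ISL1, fell, by 0.53, also when adjusted over the list alone (median -0.17, adjusted p = 0.61).

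Ribosome biogenesis genes fell, 24 of 27 lower and none higher (26 lower when adjusted over the list alone; median -0.69, adjusted p = 2.70e-11). RRS1 fell by 1.20, HEATR1 by 1.18, LYAR by 1.15 and TSR1 fell by 1.09, all of them factors of ribosomal subunit assembly or rRNA transcription. Nucleotide and polyamine synthesis genes fell, 20 of 23 lower and none higher (22 lower when adjusted over the list alone; median -0.73, adjusted p = 2.70e-11). CAD, the enzyme that opens pyrimidine synthesis, fell by 1.27, PFAS, of purine synthesis, by 1.20, and spermidine synthase, SRM, by 1.10. DNA replication and G1/S genes fell, 35 of 40 lower and none higher (38 lower when adjusted over the list alone; median -0.84, adjusted p = 1.71e-16). CDC25A, a phosphatase that activates CDK2, fell by 1.42, and MCM2, MCM5 and MCM7, of the replicative helicase, had changes of -1.18, -1.14 and -1.09. Mitosis genes fell, 21 of 29 lower and none higher (24 lower when adjusted over the list alone; median -0.42, adjusted p = 9.35e-06), a call lost at adjusted p = 0.1 with an estimated correlation. AURKB, a kinase of the passenger complex, fell by 0.77, and the checkpoint kinase BUB1B fell by 0.75.

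Interferon response genes rose with dominant-negative Tcf4, 18 of 22 higher and none lower (19 higher when adjusted over the list alone; median 1.12, adjusted p = 9.83e-10). RSAD2 rose by 4.51, OASL by 2.66, IFIT3 by 2.45, and OAS1, which makes the activator of RNase L, by 2.40. Cell junction genes rose, 13 of 25 higher and 2 lower, also when adjusted over the list alone (median 0.45, adjusted p = 2.70e-05). CGN, cingulin of tight junctions, rose by 4.09 ± 0.47 from 11.8 to 200, CLDN4 by 2.50 and TJP3 by 2.00, and CLDN2 fell by 2.26. MAPK output and immediate early genes rose, 14 of 22 higher and 2 lower (15 and 3 when adjusted over the list alone; median 0.59, adjusted p = 7.75e-05), a call lost at adjusted p = 0.11 with an estimated correlation. DUSP5 rose by 4.12, FOS by 2.07, EGR1 by 1.47 and DUSP1 by 1.41. Genes of p53 response and CDK inhibition rose, 7 of 22 higher and 3 lower, also when adjusted over the list alone (median 0.15, adjusted p = 0.0064), a call lost under the stricter filter (0.11). CDKN2B rose by 2.68 from 5.81 to 37.2, CDKN1A, the p21 inhibitor of CDK2, by 2.64 ± 0.12, TP53I3 by 1.59 and TP53INP1 by 1.51.

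ATF4 and ER stress genes rose slightly, 7 of 22 higher and 3 lower, also when adjusted over the list alone (median 0.29, adjusted p = 0.028), with an adjusted p = 0.34 with an estimated correlation, and the call was lost without _x_at and _s_at probe sets (0.28). DDIT4, an inhibitor of mTORC1, rose by 2.14, DNAJB9 by 1.68 and HERPUD1, of ER-associated degradation, by 1.27. Cholesterol synthesis genes rose, 7 of 16 higher and none lower, also when adjusted over the list alone (median 0.30, adjusted p = 0.0046), and this was lost at adjusted p = 0.46 with an estimated correlation. INSIG1, the sterol-sensing ER anchor, rose by 1.24, MVD by 0.83 and HMGCS1 by 0.76. IDI1 rose by 0.77 here and by 0.42 with the shRNA on an _x_at probe set, and these values became -0.21 and -0.47 without _x_at and _s_at probe sets. In the shRNA line the call of IDI1 also ended with median centring (0.37).

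No call was made for the other lists in this line. Wnt pathway components had 6 of 31 higher and 6 lower (7 and 6 when adjusted over the list alone; median -0.03, adjusted p = 0.85), and their mean (0.01) and the test pointed up. TLE3, a corepressor, fell by 0.76, and the tankyrase TNKS2 rose by 0.75. The receptor FZD5 had 0.76 here and 0.78 with the shRNA, and without _x_at and _s_at probe sets 0.24 and 0.74, neither past the test. Hypoxia and glycolysis genes had 6 of 21 higher and 3 lower, also when adjusted over the list alone (median -0.07, adjusted p = 0.61), with mean (0.15) and test pointing up. NDRG1 rose by 1.90, the glucose transporter SLC2A1 by 0.85 and hexokinase HK2 by 0.75. Notch pathway genes had 2 of 17 higher and 7 lower, also when adjusted over the list alone (median -0.24, adjusted p = 0.45). LFNG, which modifies Notch receptors, fell by 2.37, JAG2 fell by 0.74, and HES1, a Notch-induced repressor, rose by 1.64. BMP and TGF-beta response genes had 2 of 18 higher and 8 lower (3 and 8 when adjusted over the list alone; median -0.29, adjusted p = 0.3), with ID3 at -1.48, BMP7 at -1.47, SMAD9 at -1.40 and TGFB1 at -0.93.

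Of 7 fibroblast markers 1, LUM, rose with dominant-negative Tcf4, by 2.19 from 21.8 to 99.1, also when adjusted over the list alone (median 0.06, adjusted p = 0.6). Of 7 leukocyte markers 2 rose, 1 when adjusted over the list alone (median 0.39, adjusted p = 0.45). CD74, the invariant chain of MHC class II, rose by 1.96 from 3.92 to 15.2 (1.23 with the offset), a call lost without dominant-negative Tcf4 induced replicate 2 (1.80) or uninduced replicate 2 (1.16), and when only the arrays compared were fitted (1.96). CORO1A rose by 0.80, and its call was lost without shRNA induced replicate 3 or any shRNA uninduced replicate (0.80 each), without dominant-negative Tcf4 induced replicate 2 or 3, and without any dominant-negative Tcf4 uninduced replicate (0.65 to 0.89). It was also lost with median centring (0.79), the offset (0.65) and array quality weights (0.75), with no filter on dim genes, and when only the arrays compared were fitted. Of 11 reference genes 1 rose and 1 fell, also when adjusted over the list alone (median -0.04, adjusted p = 0.93), with B2M at 0.27, a call lost with median centring (0.26).

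The same limma test was used. As in the shRNA line, cells with doxycycline alone were not analysed here.

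**Figure D3:**
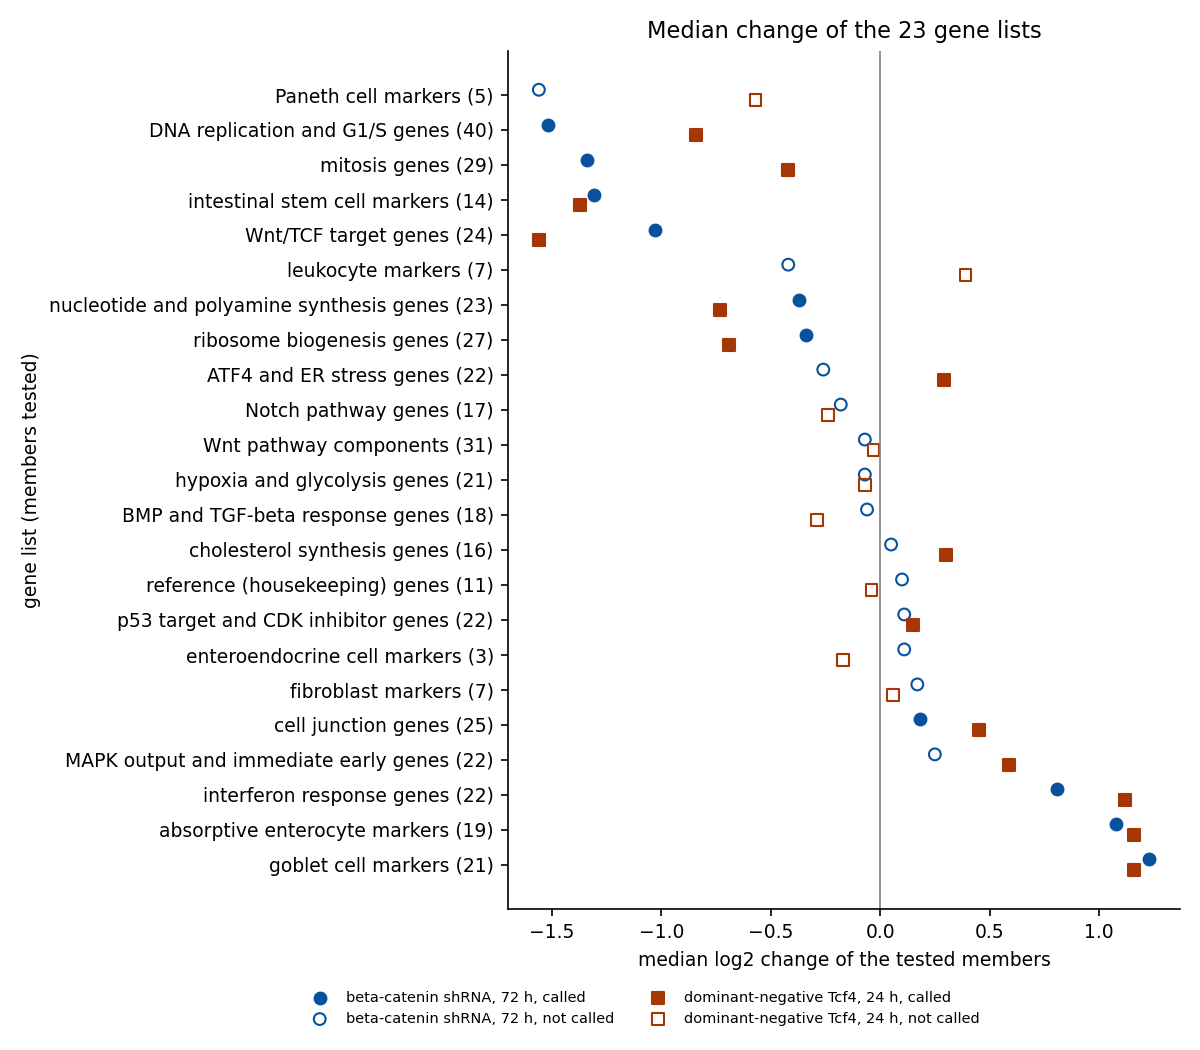
Median log2 change (x axis, induced minus uninduced) of each of the 23 gene lists (y axis, number of members tested in brackets) with the β-catenin shRNA (circles) and dominant-negative Tcf4 (squares), filled where the list's adjusted p was under 0.05. DNA replication genes stood at -1.52 and -0.84, mitosis genes at -1.34 and -0.42, and ribosome biogenesis genes at -0.34 and -0.69.

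The overlap of both responses bears on which genes depend on the pathway whichever way it is blocked. Both lines were induced with doxycycline, and no arrays with doxycycline alone were used here. An effect of the inducer would also be shared, so a shared change is not by itself a sign of dependence on the pathway. Falling together were the stem cell factor ASCL2 (-3.07 and -3.81, shRNA first), EPHB3 (-2.55 and -2.88), C2CD4A (-2.44 and -4.06), SMOC2 (-2.42 and -2.43), CEMIP (-3.52 and -2.20) and the crypt claudin CLDN2 (-2.04 and -2.26). LRP4 (-2.89 and -1.99), TMEM80 (-2.78 and -1.90), PNMA3 (-2.88 and -2.52) and RETNLB (-3.49 and -2.63) belonged to the same group. Rising together were FABP1 (7.23 and 3.66), TFF2 (4.98 and 3.84), the placental and epithelial protein PLAC8 (4.35 and 2.87), TM4SF4 (5.33 and 3.33) and ARL14 (4.96 and 2.84). EMP1, an epithelial membrane protein (3.61 and 3.97), MALL (3.13 and 3.39), ZBTB7C (4.08 and 5.28), the phosphatase PTPRH (3.47 and 4.39), the ubiquitin ligase TRIM31 (3.67 and 3.41), the chloride channel protein CLIC5 (2.83 and 3.88) and VILL, a villin-like protein (3.29 and 2.77), completed the 12 with the largest shared increase. With the offset the changes were 3.40 and 4.36 for ZBTB7C, 2.54 and 2.67 for TRIM31, and 2.24 for PTPRH and 4.08 for TM4SF4 with the shRNA.

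The 12 largest shared decreases also held SLC6A18, of the amino acid transporter family, and B3GAT1, whose calls depended on the arrays and settings used. SLC6A18 changed by -2.14 and -2.25, and its call was lost without shRNA induced replicate 1 (-1.90) or uninduced replicate 2 (-1.85), without dominant-negative Tcf4 uninduced replicate 1 (-1.71), and in the latter line when only the arrays compared were fitted. With the offset its change in that line was -1.26. B3GAT1 changed by -2.64 and -2.16. Its call with the shRNA was lost without shRNA induced replicate 1 (-1.85) or 3 (-2.42) or uninduced replicate 1 (-2.66) or 2 (-2.58). With dominant-negative Tcf4 it was lost without dominant-negative Tcf4 induced replicate 1 (-1.96) or 2 (-1.76), or uninduced replicate 2 (-2.04) or 3 (-1.79). It was also lost without shRNA induced replicate 3 or any shRNA uninduced replicate (-2.16 each), with quantile normalization (-2.17) and with the offset (-1.21). No filter on dim genes, leaving out _x_at and _s_at probe sets, a fit without the variance trend and a fit of only the arrays compared ended that call too (-2.16 each).

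In all 1199 genes fell in both lines where 431 would be expected if the calls were independent, and 1041 rose in both where 329 would be expected. The odds ratios were 8.78 (95% interval 7.91 to 9.74) and 10.21 (9.14 to 11.40). Only 88 genes fell with the shRNA and rose with dominant-negative Tcf4, against 345 expected, and 104 did the reverse, against 411 (two-sided Fisher's exact p = 9.50e-79 and 8.48e-97). Across all genes tested, Pearson's r and Spearman's rho between both sets of log2 changes were 0.46 each, and 66.32% of genes had the same sign. Among the 2432 genes called in both, r was 0.78 and 92.11% had the same sign. Genes are not independent replicates, so these values describe how alike the responses are, and no control array is shared between them. With no filter on dim genes r was 0.23, and with the stricter filter 0.58.

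**Figure D4:**
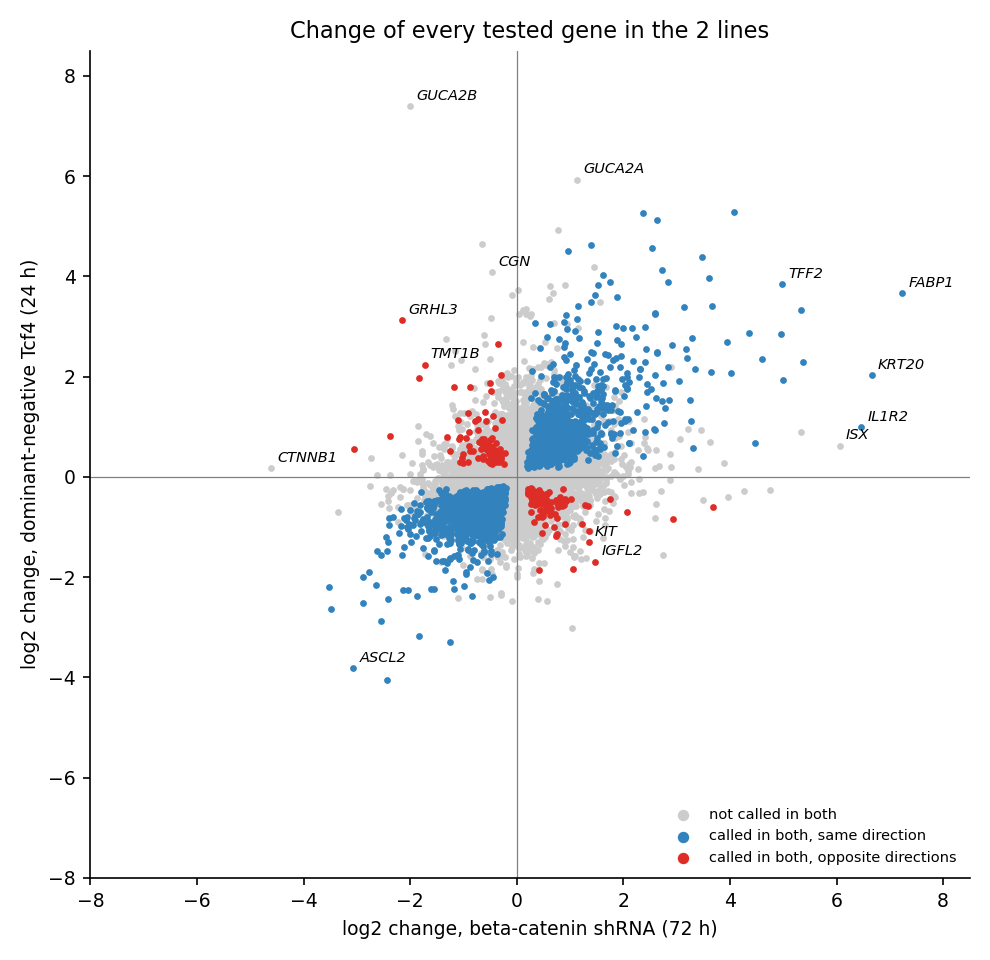
Log2 change of each of 12386 genes with the β-catenin shRNA at 72 h (x axis) against that with dominant-negative Tcf4 at 24 h (y axis), induced minus uninduced, coloured by whether the gene was called in both comparisons with the same or the opposite sign. Of 2432 genes called in both, 2240 moved the same way and 192 the opposite way.

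The genes that moved in opposite directions included TMT1B, a thiol methyltransferase (-1.73 ± 0.13 and 2.24 ± 0.13), CIDEB, a lipid droplet protein (-1.84 and 1.98), and TOX3, an HMG-box factor (-1.17 and 1.80). IGFL2, of the insulin growth factor-like family (1.47 and -1.69), and the receptor tyrosine kinase KIT (1.35 and -1.30) moved the other way. GRHL3, a transcription factor of epithelial barriers, changed by -2.15 ± 0.66 and 3.13 ± 0.66, and its call with the shRNA was lost without shRNA induced replicate 2 (-1.66), uninduced replicate 1 (-2.02) or uninduced replicate 3 (-2.06). ID1, which fell by 2.37 with the shRNA, rose by 0.81 with dominant-negative Tcf4, and CDKN1A changed by -0.36 and 2.64. With median centring of the arrays 106 genes had opposite calls in place of 192. At least a 2-fold change in both lines was seen for 9 of the 192.

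Whether the 2 perturbations act alike was tested gene by gene as the difference of their log2 changes, shRNA minus dominant-negative Tcf4. GUCA2B differed by -9.40 ± 1.15, as it rose by 7.39 with dominant-negative Tcf4 while its change of -2.01 with the shRNA did not pass (adjusted p = 0.067). GUCA2A differed by -4.80 ± 0.99 (changes of 1.13, adjusted p = 0.24, and 5.93). In the shRNA line both genes lay near the floor, with GUCA2B at 0.6 to 12 over its 6 arrays, so the size of these differences is poorly determined. With the offset the difference was -7.43 for GUCA2B, and for 2 other dim genes, GDPD3 and GRHL3, -4.14 and -4.13. Without shRNA uninduced replicate 3 both changes with the shRNA passed (-2.54 for GUCA2B, 2.16 for GUCA2A), as did GUCA2B without dominant-negative Tcf4 uninduced replicate 2 (-2.01) and GUCA2A without shRNA induced replicate 2 (1.84) or with array quality weights (1.85). CGN differed by -4.56 (changes of -0.47, adjusted p = 0.49, and 4.09), and GDPD3 by -5.29 (changes of -0.65, adjusted p = 0.56, and 4.64). GRHL3, with its opposite changes (-2.15 and 3.13), differed by -5.28. Its call with the shRNA was lost without shRNA induced replicate 2 (-1.66) or uninduced replicates 1 (-2.02) or 3 (-2.06).

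Higher with the shRNA were IL1R2 (difference 5.48 ± 0.24), ISX (5.44 ± 0.38), CA1 (5.03 ± 0.48) and KRT20 (4.63 ± 0.36). IL1R2 and KRT20 rose in both lines, by 6.46 and 0.99 and by 6.66 and 2.03. The changes of CA1 (-0.27, adjusted p = 0.58) and ISX (0.62, adjusted p = 0.087) did not pass with dominant-negative Tcf4, though ISX passed without dominant-negative Tcf4 induced replicate 3 (0.89) and without the variance trend. CTNNB1, the target of the shRNA, differed by -4.78 ± 0.15. In all 2185 genes (17.64%) differed, 1118 with the higher change under the shRNA and 1067 with the lower. With median centring 1497 differed, 645 higher and 852 lower, so that split depended on the scaling.

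**Figure D5:**
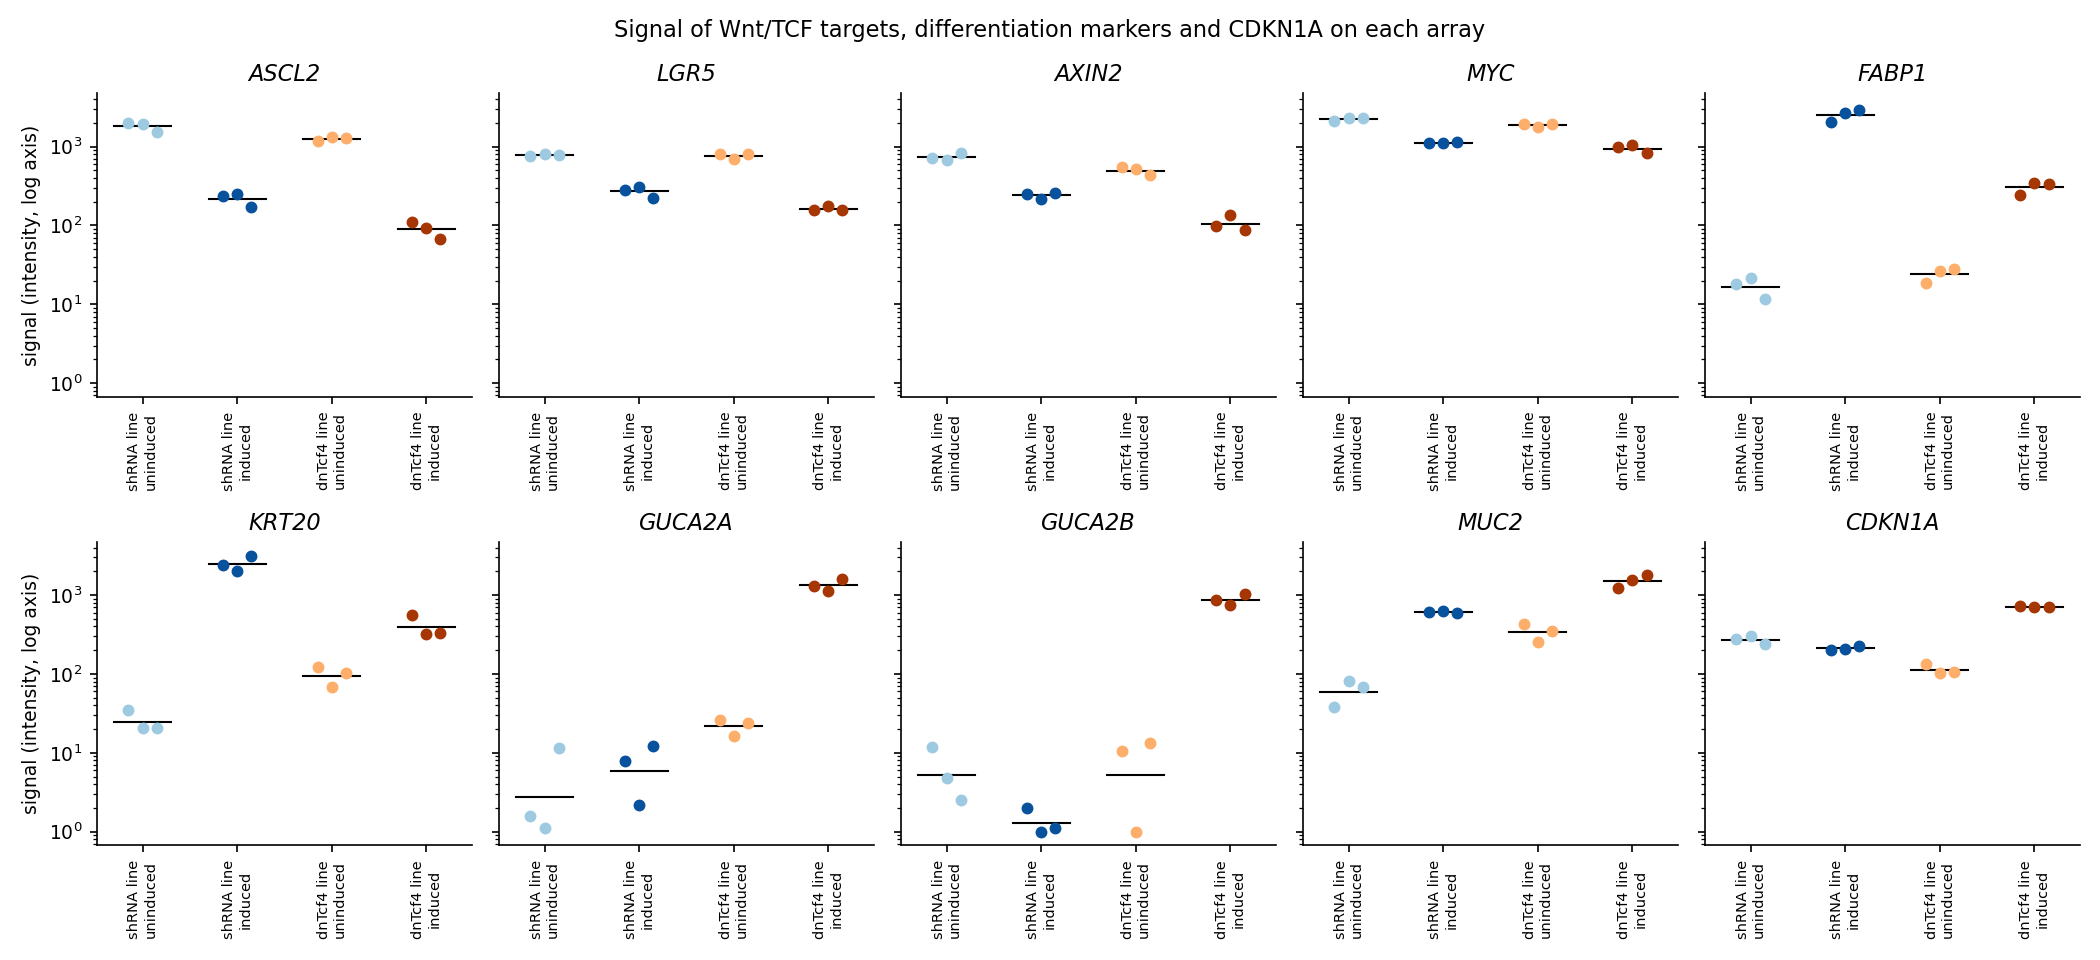
Signal of each array (points, log10 axis, arbitrary intensity units, values under 1 drawn at 1; lines are geometric means of 3 arrays) for 10 named genes in the 4 groups. ASCL2 fell in both lines, whereas GUCA2B rose from 5.19 to 868 with dominant-negative Tcf4, and KRT20 rose from 24.5 to 2480 with the shRNA and from 95 to 388 with dominant-negative Tcf4.

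Of the gene lists, 8 differed between both responses. DNA replication genes (median difference -0.70, adjusted p = 4.24e-16) and mitosis genes (-0.85, adjusted p = 1.93e-19) fell further with the shRNA, with CCNA2 differing by -1.08 and BIRC5 by -1.26. Only the mitosis list kept its call with an estimated correlation, where the values were adjusted p = 0.11 for replication and 0.03 for mitosis. Ribosome biogenesis genes (0.31, adjusted p = 0.003) and nucleotide synthesis genes (0.31, adjusted p = 0.012) fell further with dominant-negative Tcf4, HEATR1 differing by 0.99 and CAD by 1.04. Their calls were lost at adjusted p = 0.19 and 0.53 with an estimated correlation. Interferon response genes rose more with dominant-negative Tcf4 (-0.51, adjusted p = 0.0052, and adjusted p = 0.28 with an estimated correlation), led by RSAD2 (-3.54). ATF4 and ER stress genes (-0.38, adjusted p = 7.91e-05), MAPK output genes (-0.35, adjusted p = 0.006) and cholesterol synthesis genes (-0.17, adjusted p = 0.035) were also relatively higher with dominant-negative Tcf4, with adjusted p = 0.19, 0.34 and 0.58 with an estimated correlation. Line, construct and time after induction change together here, so a difference cannot be assigned to 1 of them.

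The uninduced lines were compared to see how far their arrays differ without induction. Uninduced arrays belong to the 72 h time in the shRNA line and the 24 h time in the other. Line and time in culture thus go together, and a difference cannot be assigned to the derivatives alone. The uninduced arrays differed in 4625 genes (37.34%), 2089 higher in the dominant-negative Tcf4 line and 2536 lower. This split depended on the scaling: with each array centred on its median, which moved the median log2 difference of all genes from -0.03 to 0.09, 2426 genes were higher and 1668 lower of 4094. Higher in the dominant-negative Tcf4 line were ADIRF, a regulator of adipogenesis (signal 1780 against 21), the nucleosome-binding HMGN3 (1260 against 7.06), CADPS, a factor of vesicle exocytosis (218 against 1.8), CA2 (129 against 1.73) and NIBAN1 (137 against 1.63). KLHL13, a ubiquitin ligase adaptor, lay at the floor of 1 in all 3 arrays of the shRNA line and was at least 302-fold higher in the other, or 70.7-fold with the offset. Higher in the shRNA line were CYB5A, cytochrome b5 (1330 against 1.56), PIGR, which carries immunoglobulin A across epithelium (5220 against 26.3), NKX2-3, a gut homeobox factor (307 against 2.16), NES, nestin (277 against 3.03), ZNF32 (155 against 1.28) and LINC02241 (166 against 2.37).

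Several epithelial genes named for the inductions started from unlike levels, and these were chosen after their values were seen. TFF1 was at 828 in the uninduced dominant-negative Tcf4 line and 59.1 in the uninduced shRNA line (log2 difference 3.81), MUC2 at 339 and 59.4 (2.51), CDH17 at 2100 and 237 (3.15), and REG1A at 7050 and 283 (4.64). TFF3, in contrast, was at 127 and 1030 (-3.03). Of the Wnt targets, DKK1 was at 145 and 8.71 (4.06) and CD44 at 2660 and 1340 (0.99), while LGR5 was at 768 and 787 (-0.04, adjusted p = 0.84).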

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

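The tests for the cell cycle and ribosome lists, for the genes with opposite changes and for the relabelled difference, and those of the shRNA as only cause and of doxycycline, were chosen or altered only after the results they concern were seen.

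The results listed here are differences between the 2 inductions, found by testing the difference of the log2 changes (shRNA minus dominant-negative Tcf4) itself. It was called for 2185 genes. To test whether equal changes in both lines would give as many, the change common to both was taken out of every array, and induced and uninduced were relabelled within each line. As many genes were found in 1 of 100 splits, the real one, and the highest other split called 0. This does not exclude chance, because the change particular to each line stayed in the arrays. Splits that mixed induced and uninduced arrays turned that change into spread, and in the only other split that kept both lines whole it cancelled. For the changes within each line and between the uninduced lines, the 10 splits of 6 arrays are too few for a share under 0.05. The real split was the 1 with as many genes in each case: 4217 against a highest other of 1 with the shRNA, 4455 against 2 with dominant-negative Tcf4, and 4625 against 0 between the uninduced lines. Each other split mixed the groups compared, which turned their difference into spread, so its low count is no support for the real one.

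Lower with the shRNA than with dominant-negative Tcf4 were GUCA2B (difference -9.40), GDPD3 (-5.29), GRHL3 (-5.28), GUCA2A (-4.80), CTNNB1 (-4.78), CGN (-4.56), TMT1B (-3.97), CIDEB (-3.82) and TOX3 (-2.96). Higher were IL1R2 (5.48), ISX (5.44), CA1 (5.03), KRT20 (4.63), IGFL2 (3.15) and KIT (2.65). Among the other 175 named genes 95 had a called difference. The decrease of GRHL3 with the shRNA was not called without shRNA induced replicate 2 (-1.66), uninduced replicate 1 (-2.02) or uninduced replicate 3 (-2.06). Changes with the shRNA became called for GUCA2A without shRNA induced replicate 2 (1.84) or uninduced replicate 3 (2.16) and with array quality weights (1.85), and for GUCA2B without shRNA uninduced replicate 3 (-2.54) or dominant-negative Tcf4 uninduced replicate 2 (-2.01). The change of ISX with dominant-negative Tcf4 became called without its induced replicate 3 (0.89).

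The lists that differed were DNA replication and G1/S genes (median difference -0.70), mitosis genes (-0.85), ribosome biogenesis genes (0.31), nucleotide and polyamine synthesis genes (0.31), interferon response genes (-0.51), ATF4 and ER stress genes (-0.38), cholesterol synthesis genes (-0.17) and MAPK output and immediate early genes (-0.35). With an estimated correlation the mitosis list alone kept its call (adjusted p = 0.03).

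Cell cycle genes fell further with the shRNA, and ribosome biogenesis genes with dominant-negative Tcf4. A single response of different overall size was examined through the mitosis genes. In that case 1 factor between the lines (mean list change with the shRNA over that with dominant-negative Tcf4) would serve all lists. This factor was 3.32 for mitosis genes (95% Fieller interval over arrays 2.26 to 5.87) and 0.85 for Wnt/TCF targets (0.69 to 1.04). These intervals do not overlap, but the mitosis list was taken because its change differed between the lines. A factor apart from that of the targets was favoured by this choice, so the test cannot decide. For ribosome biogenesis genes the factor was 0.54 (0.38 to 0.73), which overlaps the interval of the Wnt/TCF targets. The ribosome list is therefore not set apart from those targets by its factor. For the mitosis and ribosome lists the authors' scaling is argued against as the cause. Under quantile normalization and median centring both of their median differences kept their direction and at least 0.86 of their size. The DNA replication list was not part of these checks. The difference of the ribosome list rests on the preset correlation and was lost with an estimated one (adjusted p = 0.19). A candidate explanation that stays open is the longer time of the shRNA arrays, 72 h against 24 h, together with the difference of line and construct, none of which this design separates.

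Of the genes called in both lines, 192 moved in opposite directions. A faulty or cross-hybridizing probe set is argued against as the general cause, because 64.84% of 182 other probe sets showed both signs, and so did 73.39% with 1 other probe set per gene (95% Wilson interval 64.41 to 80.79; chance gives 25%), though only 109 of these genes had another probe set and the rest were not tested. As to noise at low signal, 91.67% of the 192 genes (interval 86.89 to 94.81) had a mean signal at or above the 75th percentile of probe sets. The share was 88.48% of genes called in both lines with the same sign and 63.84% of all genes tested. Most of the 192 genes were thus not dim. Calls in both lines favour bright genes, however, so these shares cannot decide whether such noise adds to the opposite calls. Time after induction, with 0 times measured in both lines, cannot be told apart from line and construct. With median centring 106 genes had opposite calls, so their number depends in part on the scaling.

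Interferon response genes rose in both lines. The shRNA itself, double-stranded RNA, as the only cause of both rises does not cover the line that makes none (median 1.12, adjusted p = 9.83e-10). That rise is part of the pattern itself, so it does not test the cause of the rise in the shRNA line. The authors' scaling is argued against, since the list's median after quantile normalization was at least 0.97 of its value before in both lines. Doxycycline exposure cannot be told apart from either construct, because 0 arrays of cells given doxycycline without a construct were among those used. In the shRNA line the rise was not called with an estimated correlation (adjusted p = 0.1).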

How the results depend on the processing

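All alternatives reported here were chosen before the data were examined, and none was added later. Leaving out each array in turn kept every count within 1.5 times its value: 3543 to 4337 genes with the shRNA, 3739 to 4611 with dominant-negative Tcf4, 1754 to 2181 differing between them, 3774 to 4746 between the uninduced lines, 1938 to 2175 shared and 139 to 196 opposite, with r from 0.43 to 0.45 and 24 list calls throughout. Where a group was left with 2 arrays, they were assumed to vary like the others. Requiring a 2-fold change left 1068 genes with the shRNA (533 higher, 535 lower), 936 with dominant-negative Tcf4 (609 and 327), 748 that differed, 1289 between the uninduced lines, 290 shared and 9 opposite, as a stricter criterion must. Testing every probe set by itself gave 6853 (3325 and 3528), 7125 (3268 and 3857) and 8041 between the uninduced lines, where more features were tested. Without _x_at and _s_at probe sets 1481 genes were shared, with median centring 106 were opposite, and the correlation of the changes was 0.23 with no filter and 0.58 with the stricter one; the cause was not tested. IDI1 reversed without _x_at and _s_at probe sets, to -0.47 with the shRNA and -0.21 with dominant-negative Tcf4, read from another probe set; the cause was not tested. With a replicate block the counts were 3950 with the shRNA, 4188 with dominant-negative Tcf4, 1836 differing, 2069 shared, 164 opposite and 24 list calls. Changes with the shRNA were then called for GUCA2B (-2.01) and GUCA2A (1.13), and no longer for NKD1 (-1.73), nor with dominant-negative Tcf4 for TTK (-0.60), DLL3 (-1.23) and CORO1A (0.80). No sign of pairing by number was seen, which does not settle whether samples were paired. Group means were removed from the probe sets with a mean log2 signal at or above the median. Across these, arrays of the same number correlated at -0.03, 0.03 and -0.03 in the shRNA line and -0.02, 0.06 and -0.01 in the other. Of 6180 values of 290 changes of named genes under the alternatives, 6041 kept direction and side of the threshold, 128 kept direction and lost the call, 9 gained it and 2 reversed. For the lists, 1080 of 1102 values stayed, 9 lost and 13 gained the call and none reversed. Of those that gained it 10 did so under fry, which does not compare a list with other genes. No enteroendocrine marker passed the stricter filter, so that list has no value there. Genes near the floor limit the precision: folds from signals of a few units shrank with the offset, as for GUCA2B in the dominant-negative Tcf4 line, from 167 to 88.2.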

Other observations

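The families described here were grouped by the stem of their symbols, and these tests were chosen only after the lists had been seen. With at least 8 tested members there were 199 families and 398 tests, of which 35 were called at the preset correlation. None was called with an estimated correlation, where the lowest adjusted p was 0.16, so what follows is given as values.

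With dominant-negative Tcf4, of 49 MRPL genes, which encode proteins of the large subunit of the mitochondrial ribosome, 30 fell and none rose (median log2 change -0.33, adjusted p = 2.72e-06), and of 27 MRPS genes, for the small subunit, 17 fell and 1 rose (-0.34, adjusted p = 5.82e-05). With an estimated correlation the adjusted p = 0.43 and 0.38. Of 31 POLR genes, subunits of the RNA polymerases, 18 fell (-0.48, adjusted p = 3.81e-04, and adjusted p = 0.2 with an estimated correlation). Of 23 NUP genes, nucleoporins, 16 fell with dominant-negative Tcf4 (-0.52) and 18 with the shRNA (-0.48), with adjusted p = 0.36 and 0.4 with an estimated correlation. Of 12 mucin genes 7 rose and none fell with dominant-negative Tcf4 (2.09, adjusted p = 5.82e-05, and adjusted p = 0.2 with an estimated correlation), and of 25 SEC genes, which serve protein secretion, 11 rose (0.30, adjusted p = 5.45e-04, and adjusted p = 0.16 with an estimated correlation). Of 16 keratins (KRT) 10 rose with the shRNA (0.55) and 8 with dominant-negative Tcf4 (0.51), and of 15 annexins (ANXA) 8 (0.67) and 7 (0.46), each with an adjusted p = 0.16 with an estimated correlation. Of 8 AKR genes, aldo-keto reductases, 4 rose and 1 fell with the shRNA (1.82, adjusted p = 5.45e-04, and adjusted p = 0.2 with an estimated correlation). The medians given here kept their sign under quantile normalization and median centring.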
